A study of Mus musculus with 12 samples.

How the data were processed

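RNA of mouse embryonic stem cells of the line V6.5 was sequenced in 3 groups of 4 libraries: parental cells, Tet1kd cells and Tet2kd cells. According to the labels the knockdown cells were clones that had received a short hairpin RNA vector, were selected with puromycin on feeder cells and were picked singly, and the RNA was poly(A)-selected before library preparation for SOLiD sequencing. How many clones the 4 libraries of a knockdown came from is not given in the sources used here.

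Per the submitters' processing notes, reads were aligned with TopHat2 (version 2.0.0), handled with SAMtools (version 0.1.18) and compared by the authors with DESeq (no version given), on the genome builds mm9 and NCBIM37. The authors deposited a gene table and an exon table for each knockdown against parental. The gene tables give, per the file headers, a mean signal of each group (normalized count, reads divided by a size factor), a ratio (fold, knockdown over parental), its log2 value and a p-value with its adjusted p-value from each of 2 tests. The exon tables give, per the file headers of DEXSeq, a mean signal of each bin (normalized count), a log2 ratio, a p-value with its adjusted p-value and a dispersion score. The log2 values and ratios of the deposited gene tables equalled those computed from the group means, and the adjusted p-values equalled the Benjamini-Hochberg adjustment of their p-values. The parental means of the 2 gene tables differed by 1 factor, as different size factors give, so levels are compared only within a table. The deposited log2 ratio of exon use followed its header (parental over knockdown) and is printed with the opposite sign. For 498 bins the share of the bin in the parental reads of its gene was computed from each of the 2 comparisons. This used the gene means and the deposited ratio multiplied by a series of factors. The shares from the 2 comparisons differed least at a factor of 2 (median absolute deviation 0.0116, against 0.0404 unmultiplied). Sizes are therefore given as deposited and only directions and calls are compared.

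The gene tables hold means of 4 libraries and no counts per library. Reads per library were recovered from the means, because a mean of 4 whole read numbers divided by 4 size factors takes only certain values. The steps of the lowest means gave the size factors of each group, and a gene was kept where only 1 set of whole numbers, each library within 60% (or, where several sets were found, 20%) of the group mean, matched the deposited mean and fold to their last digits. The narrower limit settled 1386 Tet1kd and 688 Tet2kd genes and favours a small spread between libraries, so the standard deviations and limma p-values of these genes lean towards small values. This was done for means up to 10000 in the knockdown groups, and the parental group used both tables together. It gave 21980 of 22004 parental genes with reads, 21208 of 21658 Tet1kd genes and 20997 of 21368 Tet2kd genes, with 99.9999%, 69.8% and 71.0% of the reads. Where parental values were recovered from 1 table alone and compared with those from both, 36144 of 37219 were answered, 36143 rightly and 1 wrongly. The recovered libraries carry letters (a to d, by size factor) because nothing ties them to the numbered samples of the labels. Standard deviations are over 4 recovered libraries and are missing for genes that were not recovered. By size factor each group was split into 2 deeper libraries (a and b) and 2 shallower libraries (c and d). This split is called the library batch here and was taken from the values, not from the labels. Deviations of libraries in different groups correlated at 0.383 to 0.589 within this library batch and at -0.542 to -0.379 across it.

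The parental libraries held 14.6, 15.9, 29.1 and 31.6 M recovered reads. The Tet1kd libraries held an estimated 15.9, 17.3, 27.6 and 39.7 M reads and the Tet2kd libraries an estimated 14.4, 15.2, 24.5 and 31.1 M reads, scaled from the recovered reads by size factor.

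The samples, gene lists, tests, thresholds and the rule for named genes were fixed before the data were examined. The test of genes was the adjusted p-value of the first of the authors' deposited tests at 0.05, and the test of exon bins was the deposited adjusted p-value at 0.05. The second deposited p-value, from a generalized linear model whose terms are not given in the sources used here, served as an alternative. The planned tests with edgeR and DESeq2 depended on counts per sample in the tables and were not run. Genes were also tested with limma (version 3.58.1, R version 4.3.3) on log2 recovered normalized counts with a pseudocount of 0.5, over genes with a mean of at least 10. This test was added after the data were examined, and it took the place of the planned approximate error for the difference between the knockdowns. On simulated data with 200 changed genes per comparison, limma called 93, 96 and 96 of 100 genes changed 2-fold and 48, 44 and 42 of 100 with a smaller simulated change in the comparisons of Tet1kd with parental, Tet2kd with parental and Tet1kd with Tet2kd, with 5, 4 and 8 false calls.

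The named genes were the TET genes, the 8 genes with the largest rise and the 8 with the largest fall past the threshold with a mean of at least 100 in the higher group, up to 3 members of each list with the smallest adjusted p, and the 8 genes called in both knockdowns in the same and the 8 in opposite directions with the largest smaller change. For exons they were the called bins of Tet1 and Tet2 and the 10 genes whose best bin had the smallest adjusted p at a mean of at least 20. Ties were broken by the larger size of the ratio. Members of lists named beside these were chosen after their values were seen: Col1a1, Col1a2, Fn1 and Mmp3 of the feeder list, Dcn in Tet2kd cells and the X-linked copies of Y-linked genes. Of the genes that this rule names 4 are not reported here, although the counts of lists and of named genes hold them. Genes with no reads in a group are given as bounds from a floor of 3 reads per library. For named genes with 1 to 12 reads in all 4 libraries of a group together, a 95% counting interval of the log2 fold change was added after the data were examined. It is exact given the pooled reads of both groups and their size factors, and it leaves out the spread between libraries.

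The fixed lists were TET, DNMT and base excision genes, naive pluripotency, primed and epiblast, trophectoderm, primitive endoderm, Nodal target and primitive streak, neuroectoderm, germline, imprinted, 2-cell-like, Polycomb complex, splicing factor, feeder fibroblast, interferon response, p53 target, glycolysis and hypoxia, cholesterol synthesis, amino acid and unfolded protein response, replication-dependent histone, ribosomal protein, mitochondrially encoded, Y-linked and cell cycle genes. Members with a mean of at least 10 were used. The median log2 fold change of a list was compared with 10000 random lists of the same size matched on mean count in 20 bins, and p-values were adjusted over all lists and both knockdowns. Each list was also tested with camera of limma with an estimated correlation between genes, over its recovered members. On simulated lists of 25 members with no shift 3 of 20 were called, and 19 of 20 with a shift of 0.3. The 3 false calls of 20 show that the random list test calls some lists with no shift.

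Chromosomes were compared by the median log2 fold change of genes with a mean of at least 100, with 100000 permutations of genes. Blocks of at least 15 neighbouring genes with a shifted mean were searched for along each chromosome, with fold changes limited to 1 and -1 on the log2 scale and 1000 permutations of gene order. This search was added after the data were examined. Gene names, chromosomes, gene order, transcript length and GC content came from GENCODE release M21, which uses another genome build, so no positions are given. Of the gene identifiers 905 join overlapping genes whose reads are not separated. Python (version 3.11.15), NumPy (version 2.4.6), pandas (version 2.3.3), SciPy (version 1.17.1) and statsmodels (version 0.14.6) were used.

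Most alternatives changed 1 choice at a time: the threshold, the lowest mean count, a fold limit, the scaling, the adjustment, the random lists, the statistic of a list, the libraries left out, the library batch as a term, and the genes of the blocks and of the Y chromosome. Some changed more than 1: limma on the recovered reads changed the test, the values and the genes tested, camera changed the test and the members, and the fold limit on the multiplied exon ratio changed the scale and the limit. List members with a parental mean count of at least 100 were compared with random lists matched on the parental mean.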

Results

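Gene expression was measured by RNA sequencing in V6.5 mouse embryonic stem cells and in cells of the same line that carried a stable short hairpin RNA against Tet1 (Tet1kd) or Tet2 (Tet2kd). Tet1 and Tet2 are dioxygenases that oxidize 5-methylcytosine to 5-hydroxymethylcytosine. Each of the groups (parental, Tet1kd and Tet2kd) held 4 libraries of poly(A)-selected RNA, and each knockdown was compared with the same 4 parental libraries. No group carried a control hairpin or an empty vector. Effects of the vector, the selection and the picking of clones therefore cannot be told apart from those of the knockdown. The parental libraries held from 14.6 to 31.6 M reads assigned to genes. The Tet1kd libraries held an estimated 15.9 to 39.7 M reads and the Tet2kd libraries an estimated 14.4 to 31.1 M reads.

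The targeted gene was lower in every library of its own knockdown. The normalized read count of Tet1 (ENSMUSG00000047146, chromosome 10) was 27235 ± 2261 in the parental libraries (SD, n = 4) and 6860 ± 722 in the Tet1kd libraries (SD, n = 4). The 4 parental libraries lay between 25090 and 29709 and the 4 Tet1kd libraries between 6215 and 7540. Tet1 kept 25.2% of its parental mean in the authors' deposited table, with a log2 fold change of -1.99 and an adjusted p of 1.19e-68. The normalized read count of Tet2 (ENSMUSG00000040943, chromosome 3) was 7837 ± 308 in the parental libraries (SD, n = 4) and 3992 ± 206 in the Tet2kd libraries (SD, n = 4). The 4 parental libraries lay between 7507 and 8192 and the 4 Tet2kd libraries between 3815 and 4247. In the authors' deposited table Tet2 kept 50.9% of its parental mean, with a log2 fold change of -0.97 and an adjusted p of 3.08e-30.

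The TET genes that were not targeted were compared in the same way. Tet2 rose slightly in Tet1kd cells, by 0.24 on the log2 scale in the authors' deposited table (adjusted p = 0.0186). Tet1 had a log2 fold change of 0.22 in Tet2kd cells that was not past the threshold (adjusted p = 0.104 in the authors' deposited table), while the adjusted p of their second test was listed as 0. Tet3 (ENSMUSG00000034832, chromosome 6), expressed at a far lower level, was at 206 ± 10.7 in the parental libraries (SD, n = 4) and at 366 ± 24.5 in the Tet1kd libraries (SD, n = 4). The authors' deposited table gave it a log2 fold change of 0.83 in Tet1kd cells (adjusted p = 6.45e-09) and of 0.07 in Tet2kd cells (adjusted p = 0.976). The difference between the knockdowns in Tet3 passed a direct test with limma, at 0.76 on the log2 scale (adjusted p = 7.22e-05).

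**Figure D1:**
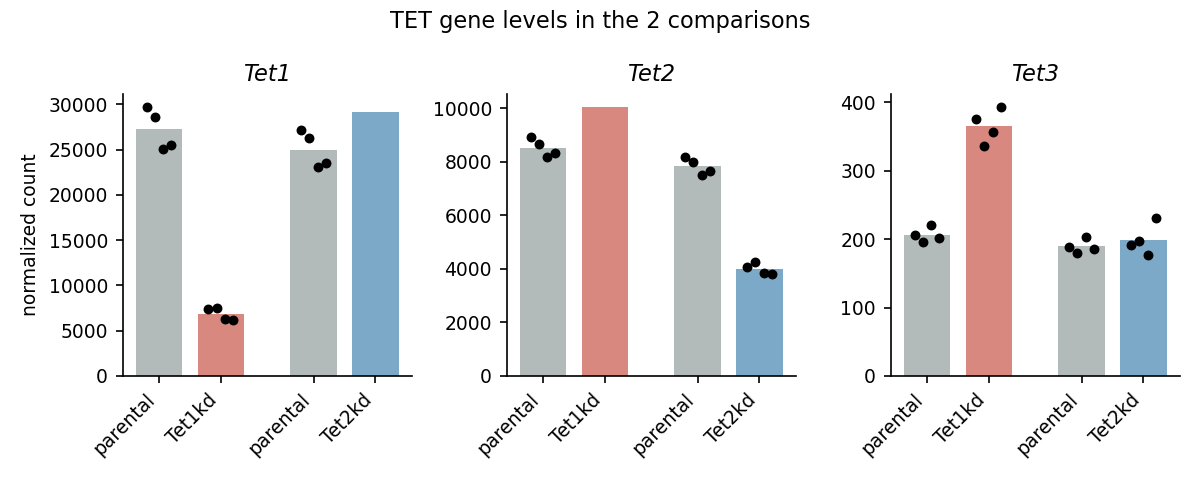
Normalized read counts (linear axis from 0) of Tet1, Tet2 and Tet3 in parental, Tet1kd and Tet2kd cells: bars are group means, dots are single libraries, and bars with no dots for a knockdown are groups whose single libraries were not recovered. Tet1 stood at 25.2% of its parental mean in Tet1kd cells and Tet2 at 50.9% in Tet2kd cells.

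The first comparison asked which genes change when Tet1 is depleted. The caudal homeobox gene Cdx1 and the secreted growth factor carrier Fgfbp1 nearly disappeared. Fos, Fosb and Egr2, transcription factors of the immediate-early response to growth signals, were among the largest rises. In total 7037 of 23120 genes tested changed in the authors' deposited table, of which 3505 were higher and 3532 lower in Tet1kd cells. At least a 2-fold change was reached by 928 of the higher and 982 of the lower genes.

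Cdx1 was at 648 ± 63.9 normalized counts in the parental libraries and at 28.7 ± 12.6 in the Tet1kd libraries (SD, n = 4 each). Its log2 fold change was -4.50 in the authors' deposited table (adjusted p = 2.77e-125). Fgfbp1 was at 1098 ± 30 and 52.8 ± 13.2 (SD, n = 4 each). Its log2 fold change in the authors' deposited table was -4.38 (adjusted p = 4.38e-227). Pax6, a transcription factor of eye and neural development, had a log2 fold change of -4.09 in the authors' deposited table, and the mitochondrial dimethylglycine dehydrogenase Dmgdh one of -3.64. Decorin (Dcn), a matrix proteoglycan of fibroblasts and an imprinted gene in mouse, had a log2 fold change of -4.98 in the authors' deposited table (adjusted p = 1.4e-89). Fos had a mean of 2072 normalized counts in parental cells and of 22809 in Tet1kd cells, a log2 fold change of 3.46 in the authors' deposited table (adjusted p = 6.43e-251). Egr2 was at 123 ± 19.5 in the parental and at 982 ± 33.3 in the Tet1kd libraries (SD, n = 4 each). The log2 fold change of Egr2 was 3.00 and that of Fosb 3.14 in the authors' deposited table. The other genes with the largest rises in the authors' deposited table were Dcdc2a (4.47), the plasma membrane calcium pump Atp2b2 (3.55), Prom2 (3.54), the GDNF family receptor Gfra2 (3.18) and Paqr5 (3.09), each as a log2 fold change.

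The Y-linked genes Uty, Eif2s3y and Ddx3y nearly disappeared from Tet1kd cells. Their log2 fold changes in the authors' deposited table were -6.25, -4.77 and -4.61, so that 1.31%, 3.67% and 4.09% of the parental means remained. All 3 measured members of the Y-linked list fell (median -4.77, adjusted p = 0.00092). The adjusted p of this list was 0.124 with an estimated correlation, and adjusted over the list alone 3 members were lower. Ddx3y shares much of its sequence with the X-linked Ddx3x, so its remaining reads are uncertain. Ddx3x had a log2 fold change of -0.39 in the authors' deposited table.

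Genes of the totipotent-like state of the 2-cell embryo fell: all 8 measured members were lower in Tet1kd cells, with a median log2 fold change of -3.21 (adjusted p = 0.00092). With an estimated correlation the adjusted p was 0.14, and adjusted over the list alone 8 members were lower. The autophagy receptor gene Calcoco2 (-1.62), Tmem92 (-4.91) and Zscan4d (6.26% of the parental mean), one of a family of near-identical zinc finger genes whose reads are uncertain, had the smallest adjusted p values in the authors' deposited table. Tmem92 and Zscan4d were low in parental cells, at 24.3 ± 3.48 and 26.2 ± 7.20 normalized counts (SD, n = 4). They had 5 and 8 reads in all 4 Tet1kd libraries together, so their log2 fold changes are known only within counting intervals of -6.14 to -3.22 and -5.22 to -2.95.

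Among the lists of lineages of the early embryo, trophectoderm genes passed the test of all members in Tet1kd cells. Of 21 measured members 11 fell, 6 rose and 4 did not pass the test (median log2 fold change -1.08, adjusted p = 0.00092). Its adjusted p = 0.346 with an estimated correlation, and adjusted over the list alone 11 were lower and 6 higher. Among the 10 members with a parental mean count of at least 100 the median was -0.52 (adjusted p = 0.0042). Among those with a mean of at least 100 over both groups, a limit that falling genes leave, it was 0.24 (adjusted p = 0.396). The keratin gene Krt18 (-1.41) and Bmp4 (-1.08), a secreted signal, fell in the authors' deposited table, and the transcription factor gene Tfap2c (0.85) rose. Plac1, a gene of the placenta, had no reads in any Tet1kd library and was at least 9.14-fold lower in Tet1kd cells, from a floor of 3 reads per library.

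Naive pluripotency genes went both ways, with 10 of 27 higher, 7 lower and 10 neither (median 0.02, adjusted p = 0.277), and adjusted over the list alone 11 were higher and 9 lower. The pluripotency factor gene Klf4 (1.20) and the AKT coactivator gene Tcl1 (1.09) rose and Fbxo15 (-0.96) fell in the authors' deposited table. Of the 13 primed and epiblast genes 4 were higher and 5 lower (median -0.04, adjusted p = 0.893), and adjusted over the list alone these numbers were 4 and 5. Otx2 (1.52), a transcription factor of the anterior epiblast, and the Wnt effector gene Lef1 (1.39) rose and the zinc finger gene Zic2 (-1.49) fell in the authors' deposited table. Of 17 primitive endoderm genes 7 were higher and 5 lower (median 0.01, adjusted p = 0.893), and adjusted over the list alone 7 and 5. Members with a mean count of at least 100 over both groups, a limit that rising genes enter, had a median of 0.37 (adjusted p = 0.0222), while the 12 with a parental mean count of at least 100 had one of -0.05 (adjusted p = 0.946). The endocytic receptor gene Cubn (2.26), the laminin gene Lama1 (0.90) and the basement membrane collagen gene Col4a1 (0.93) rose in the authors' deposited table.

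Of 13 Nodal target and primitive streak genes 4 were higher and 5 lower (median 0.00, adjusted p = 0.996), and adjusted over the list alone 4 and 5. The mean over these genes was -0.59. Brachyury (T), the transcription factor that marks early mesoderm, had a log2 fold change of -3.63 in the authors' deposited table (adjusted p = 4.79e-39), while the Nodal antagonist gene Lefty1 (1.09) and the inhibitory Smad gene Smad7 (0.61) were higher there. Of 11 neuroectoderm genes 3 were higher and 5 lower (median -0.33, adjusted p = 0.161), and adjusted over the list alone 3 and 5. Besides Pax6, the intermediate filament gene Nes (-2.03) fell and the oligodendrocyte factor gene Olig2 (1.36) rose in the authors' deposited table. Of 23 germline genes 4 were higher and 7 lower (median -0.31, adjusted p = 0.069), and adjusted over the list alone 4 and 9. Against random lists not matched on expression the adjusted p of this list was 0.0374. Dpep3 (2.40) and the meiotic cohesin gene Stag3 (0.54) rose and Tex19.1 (-0.65) fell in the authors' deposited table.

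Imprinted genes fell as a group, with 16 of 31 lower, 6 higher and 9 neither (median -0.32, adjusted p = 0.00977). For this list adjusted p = 0.0832 with an estimated correlation, and adjusted over the list alone 17 were lower and 6 higher. The paternally expressed genes Peg10 (-1.68) and Peg3 (-1.39) fell in the authors' deposited table, as did Dcn, which the feeder fibroblast list also holds. Of 17 TET, DNMT and base excision genes 4 were higher and 4 lower (median -0.05, adjusted p = 0.996), and adjusted over the list alone 4 and 5. The de novo methyltransferase gene Dnmt3a (-0.80) fell and the isocitrate dehydrogenase gene Idh2 (0.57) rose in the authors' deposited table. Of 32 Polycomb complex genes 5 were higher and 11 lower (median -0.05, adjusted p = 0.996), and adjusted over the list alone 6 and 11. The histone methyltransferase gene Ezh2 (-1.04) and its partners Aebp2 (-0.67) and Mtf2 (-0.64) fell in the authors' deposited table.

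Splicing factor genes fell as a group, with 21 of 38 lower, 3 higher and 14 neither (median -0.28, adjusted p = 0.00552). The adjusted p was 0.351 with an estimated correlation, and adjusted over the list alone 21 were lower and 3 higher. Tra2a (-0.87) and the ribonucleoprotein gene Hnrnpa2b1 (-0.77) fell in the authors' deposited table, and the epithelial splicing regulator gene Esrp1 (0.97) rose. Cell cycle genes went both ways, with 6 of 31 higher and 13 lower (median -0.13, adjusted p = 0.591), and adjusted over the list alone 6 and 13. Their mean was -0.29 and passed the test against random lists (adjusted p = 0.0227), but adjusted p = 0.313 with an estimated correlation. Myc (-2.61), the replication helicase gene Mcm2 (-1.23) and cyclin E1 (Ccne1, -1.05) had the smallest adjusted p values of the list in the authors' deposited table. Ezh2, Tra2a, Hnrnpa2b1, Mcm2, Hk2 and Kdm3a lie in the shifted block of chromosome 6 described with the chromosomes, and Tet3, which rose, lies there too.

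Targets of the tumour suppressor p53 fell, with 14 of 25 lower, 1 higher and 10 neither (median -0.32, adjusted p = 0.00526). This call held with an estimated correlation (adjusted p = 0.0482 with an estimated correlation), and adjusted over the list alone 16 were lower and 1 higher. The p53 ubiquitin ligase gene Mdm2 (-0.87), Plk3 (-0.62) and the receptor gene Eda2r (-0.95) fell in the authors' deposited table.

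Genes of the feeder fibroblast list also fell, with 21 of 30 lower, 3 higher and 6 neither (median -0.64, adjusted p = 0.00092). The list stands for the other cell type in the cultures on which the clones were selected. It also holds genes with many reads, such as fibronectin (Fn1), at a parental mean of 45462 in the Tet2kd comparison. The call held with an estimated correlation (adjusted p = 0.0482 with an estimated correlation), and adjusted over the list alone 22 were lower and 3 higher. Dcn (-4.98), the protease gene Mmp3 (-3.41) and the smooth muscle actin gene Acta2 (-1.72) were among the members that fell in the authors' deposited table. The abundant collagen genes Col1a1 (-0.31) and Col1a2 (-0.36) fell little and fibronectin (Fn1, 0.51) rose in the authors' deposited table.

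Of 26 amino acid and unfolded protein response genes 15 rose, 4 fell and 7 did neither (median 0.37, adjusted p = 0.00092). Its adjusted p = 0.2 with an estimated correlation, and adjusted over the list alone 16 were higher and 4 lower. The glutathione-degrading enzyme gene Chac1 (2.22), Nupr1 (1.38) and Vegfa (1.29), which encodes a vascular growth factor, rose in the authors' deposited table. Of 28 glycolysis and hypoxia genes 14 rose, 6 fell and 8 did neither (median 0.27, adjusted p = 0.00153). For this list adjusted p = 0.456 with an estimated correlation, and adjusted over the list alone 15 were higher and 6 lower. The mean log2 fold change in place of the median ended this call (0.17, adjusted p = 0.113). The hexokinase gene Hk2 (-1.22) and the histone demethylase gene Kdm3a (-1.67) fell in the authors' deposited table. Of 23 cholesterol synthesis genes 2 were higher and 5 lower (median -0.02, adjusted p = 0.996), and adjusted over the list alone 3 and 5. The sterol transfer gene Stard4 (-0.44) fell in the authors' deposited table.

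The other lists had medians that did not pass the test. Of 18 interferon response genes 3 were higher and 7 lower (median -0.21, adjusted p = 0.25), and adjusted over the list alone 3 and 7. The antiviral genes Ddx58 (-0.55) and Oasl2 (-2.80) fell and Oas3 (1.09) rose in the authors' deposited table. Of 20 replication-dependent histone genes 1 was higher and 2 lower (median -0.24, adjusted p = 0.464), and adjusted over the list alone 1 and 2. Hist1h2bc (0.55) rose and Hist1h1a (-1.02) and Hist2h4 (-0.70) fell in the authors' deposited table, and the reads of such genes are uncertain because they have near-identical copies. Hist2h4 was no longer past the threshold by limma in 2 of the 8 settings that leave out 1 library, without parental replicate c (adjusted p = 0.0638) and without Tet1kd replicate a (0.0532). Of 80 ribosomal protein genes 6 were higher and 7 lower (median 0.00, adjusted p = 0.996), and adjusted over the list alone 6 and 5. Rpl39l, a copy of Rpl39 whose reads are uncertain, had a log2 fold change of 1.08 in the authors' deposited table, with Rps15a at -0.62 and Rpl7l1 at -0.43. Of 14 mitochondrially encoded genes 5 were lower and 0 higher (median -0.31, adjusted p = 0.138), and adjusted over the list alone 5 and 0. The ribosomal RNAs mt-Rnr2 (-0.73) and mt-Rnr1 (-0.60) and the transfer RNA mt-Tm (-1.43) fell in the authors' deposited table. How poly(A) selection bears on the reads of these RNAs and of the histone genes, in either knockdown, was not tested.

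Of the 80 genes named for this comparison and past the threshold, 72 had all single libraries recovered. In these 72 all 4 Tet1kd libraries lay on the side of the change, as is expected of genes chosen for passing the test. The p values measure the spread between these libraries, and the labels do not say how many clones the 4 libraries of a knockdown came from.

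The second comparison asked which genes change when Tet2 is depleted. Fewer genes changed and the changes were smaller. Besides the Y-linked genes, the largest falls included Gata6, a transcription factor of the primitive endoderm, and Id1, a target of BMP signals. The largest rises included Otx2 and the Nodal target Lefty1. In total 1638 of 22949 genes tested changed in the authors' deposited table, of which 884 were higher and 754 lower in Tet2kd cells. At least a 2-fold change was reached by 103 of the higher and 90 of the lower genes.

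Gata6 was at 112 ± 14 normalized counts in the parental libraries and at 38.4 ± 11.9 in the Tet2kd libraries (SD, n = 4 each). Its log2 fold change in the authors' deposited table was -1.54 (adjusted p = 4.74e-10). Id1 was at 813 ± 93.7 and 325 ± 38.6 (SD, n = 4 each). The authors' deposited table gave Id1 a log2 fold change of -1.32 (adjusted p = 6.86e-19). The other large falls in the authors' deposited table were Tnfsf9 (-1.38), Galnt6 (-1.37) and Arhgef26 (-1.37), each as a log2 fold change. Otx2 was at 217 ± 18.7 in the parental and at 546 ± 43 in the Tet2kd libraries, and Lefty1 at 829 ± 41.5 and 2080 ± 24.3 (SD, n = 4 each). In the authors' deposited table both had a log2 fold change of 1.33, with an adjusted p of 5.65e-25 for Otx2 and of 3.51e-45 for Lefty1. The other large rises in the authors' deposited table were the lysosomal transporter gene Slc46a3 (1.80), the presynaptic gene Pclo (1.64), Enpp2 (1.51), which encodes autotaxin, the channel gene Trpm1 (1.51), Pdlim4 (1.38) and the interferon-induced gene Ifitm1 (2.46-fold).

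The Y-linked genes were lost in this knockdown too. The log2 fold changes of Uty, Eif2s3y and Ddx3y were -5.73, -5.19 and -3.89 in the authors' deposited table, so that 1.88%, 2.75% and 6.75% of the parental means remained. All 3 measured members fell (median -5.19, adjusted p = 0.00092). With an estimated correlation the adjusted p was 0.0787, and adjusted over the list alone 3 members were lower.

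Primed and epiblast genes rose, with 8 of 13 higher, 1 lower and 4 neither (median 0.46, adjusted p = 0.00092). The call held with an estimated correlation (adjusted p = 0.0482 with an estimated correlation), and adjusted over the list alone 8 were higher and 1 lower. Otx2, Zic2 (0.86) and Lef1 (0.77) had the smallest adjusted p values in the authors' deposited table. Naive pluripotency genes shifted slightly upwards, with 4 of 27 higher, 0 lower and 23 neither (median 0.13, adjusted p = 0.00092). The adjusted p was 0.103 with an estimated correlation, adjusted over the list alone 7 were higher and 0 lower, and against random lists not matched on expression the adjusted p was 0.0692. Dppa3 (0.99), Prdm14 (0.74) and Sox2 (0.28), all members of the naive pluripotency list, rose in the authors' deposited table. Nodal target and primitive streak genes rose, with 5 of 13 higher, 1 lower and 7 neither (median 0.28, adjusted p = 0.0216). Its adjusted p = 0.0832 with an estimated correlation, and adjusted over the list alone 6 were higher and 1 lower. Lefty1, Lefty2 (1.24) and T (0.87) led this list in the authors' deposited table.

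Primitive endoderm genes fell, with 5 of 17 lower, 1 higher and 11 neither (median -0.30, adjusted p = 0.00092). For this list adjusted p = 0.103 with an estimated correlation, and adjusted over the list alone 6 were lower and 3 higher. The call was not kept among the 11 members with a parental mean count of at least 100 (median -0.01, adjusted p = 0.946). Among those with a mean of at least 100 over both groups, a limit that Gata6 and Pdgfra leave by their fall, the median was 0.03 (adjusted p = 0.721). Gata6, the growth factor receptor gene Pdgfra (-1.18) and Cubn (-1.36) fell in the authors' deposited table. Of 21 trophectoderm genes 2 were higher and 4 lower, and the median was 0.13 (adjusted p = 0.407) while the mean was -0.21 (adjusted p = 0.0419). Among the 10 members with a parental mean count of at least 100 the median was -0.20 (adjusted p = 0.0198). For all members adjusted p = 0.677 with an estimated correlation, and adjusted over the list alone 2 were higher and 5 lower. The galectin gene Lgals3 (-0.76) fell and Tfap2c (0.59) rose in the authors' deposited table. Plac1 fell to 3 reads in all 4 Tet2kd libraries together, a log2 fold change within a counting interval of -7.51 to -3.63.

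Targets of p53 fell, with 10 of 25 lower, 0 higher and 15 neither (median -0.21, adjusted p = 0.00092). The call held with an estimated correlation (adjusted p = 0.0482 with an estimated correlation), and adjusted over the list alone 12 were lower and 1 higher. Ddit4l (-0.94), the death receptor gene Tnfrsf10b (-0.69) and Mdm2 (-0.51) fell in the authors' deposited table. Cholesterol synthesis genes shifted upwards, with 2 of 23 higher, 0 lower and 21 neither (median 0.17, adjusted p = 0.00153). The adjusted p was 0.0832 with an estimated correlation, and adjusted over the list alone 4 were higher and 0 lower. The sterol sensor gene Insig1 (0.32) rose in the authors' deposited table. Replication-dependent histone genes shifted downwards, although only 1 of 21 was lower, 1 higher and 19 neither (median -0.44, adjusted p = 0.00283). Its adjusted p = 0.456 with an estimated correlation, and adjusted over the list alone 1 was lower and 1 higher. Only 1 member had a parental mean count of at least 100. The RNA was poly(A)-selected, and how this bears on the reads of histone genes was not tested, so the shift may not reflect their expression. Hist1h2bc (-0.59) fell and the linker histone gene Hist1h1c (0.55) rose in the authors' deposited table.

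The medians of the other lists did not pass the test in Tet2kd cells. Of 31 feeder fibroblast genes 11 were higher and 2 lower (median 0.08, adjusted p = 0.166), and adjusted over the list alone 12 and 3. Ccn2 (0.93), Ccn1 (0.64) and Acta2 (0.64), targets of mechanical and growth signals in fibroblasts, rose in the authors' deposited table, and Dcn was at -0.21 (adjusted p = 0.575). Of 17 TET, DNMT and base excision genes 0 were higher and 3 lower (median 0.01, adjusted p = 0.692), and adjusted over the list alone 3 and 3. Dnmt3l (-0.75), the catalytically inactive partner of the de novo methyltransferases, and Dnmt3a (-0.25) fell in the authors' deposited table. Of 11 neuroectoderm genes 2 were higher and 1 lower (median 0.04, adjusted p = 0.958), and adjusted over the list alone 3 and 2, with Map2 at 0.59, Cdh2 at 0.73 and Stmn2 at -0.24 in the authors' deposited table. Of 23 germline genes 5 were higher and 2 lower (median -0.02, adjusted p = 0.67), and adjusted over the list alone 5 and 4. The Piwi gene Piwil2 (-0.60) and the meiotic entry gene Stra8 (-1.03) fell in the authors' deposited table, while Tuba3a (0.79), a tubulin gene with a near-identical copy, rose. Of 31 imprinted genes 4 were higher and 3 lower (median 0.09, adjusted p = 0.138), and adjusted over the list alone 5 and 3, with Grb10 at -0.60, Peg3 at 0.56 and Phlda2 at -0.47 in the authors' deposited table.

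Of 9 genes of the 2-cell-like list 1 was higher and 0 lower (median -0.32, adjusted p = 0.106, or 0.0113 against random lists not matched on expression), and adjusted over the list alone 1 and 1, with Calcoco2 at 0.33 in the authors' deposited table. Of 32 Polycomb complex genes 1 was higher and 2 lower (median 0.01, adjusted p = 0.745), and adjusted over the list alone 2 and 2, with Cbx8 at -1.95, Jarid2 at -0.34 and Phc1 at 0.26 in the authors' deposited table. Of 38 splicing factor genes 2 were higher and 2 lower (median -0.05, adjusted p = 0.464), and adjusted over the list alone 2 and 3, with Esrp2 at 0.45, Esrp1 at 0.27 and Khdrbs1 at -0.28 in the authors' deposited table. Of 17 interferon response genes 1 was higher and 1 lower (median 0.10, adjusted p = 0.407), and adjusted over the list alone 1 and 1, with Ifitm3 at 0.45 and Ifit2 at -1.26 in the authors' deposited table. Of 28 glycolysis and hypoxia genes 1 was higher and 3 lower (median 0.00, adjusted p = 0.893), and adjusted over the list alone 1 and 3. The oxygen sensor genes Egln1 (-0.51) and Egln3 (0.42) and the hypoxia target Ndrg1 (-0.36) changed in the authors' deposited table.

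Of 26 amino acid and unfolded protein response genes 2 were higher and 2 lower (median 0.05, adjusted p = 0.242), and adjusted over the list alone 3 and 2, with Chac1 at 0.75, Herpud1 at 0.37 and the chaperone gene Hspa5 at -0.34 in the authors' deposited table. Of 80 ribosomal protein genes 2 were higher and 5 lower (median -0.02, adjusted p = 0.893), and adjusted over the list alone 2 and 5, with Rpl39l at -1.25, Rpl14 at -0.65 and Rps20 at 0.41 in the authors' deposited table. Of 14 mitochondrially encoded genes 1 was lower and 0 higher (median -0.02, adjusted p = 0.996), and adjusted over the list alone 1 and 0, with mt-Tm at -1.09 in the authors' deposited table. Of 31 cell cycle genes 3 were higher and 2 lower (median -0.06, adjusted p = 0.471), and adjusted over the list alone 3 and 3. The mitotic kinase gene Aurka (-0.44) fell and Mycn (0.38) and the cell cycle inhibitor gene Cdkn2a (0.67) rose in the authors' deposited table.

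**Figure D2:**
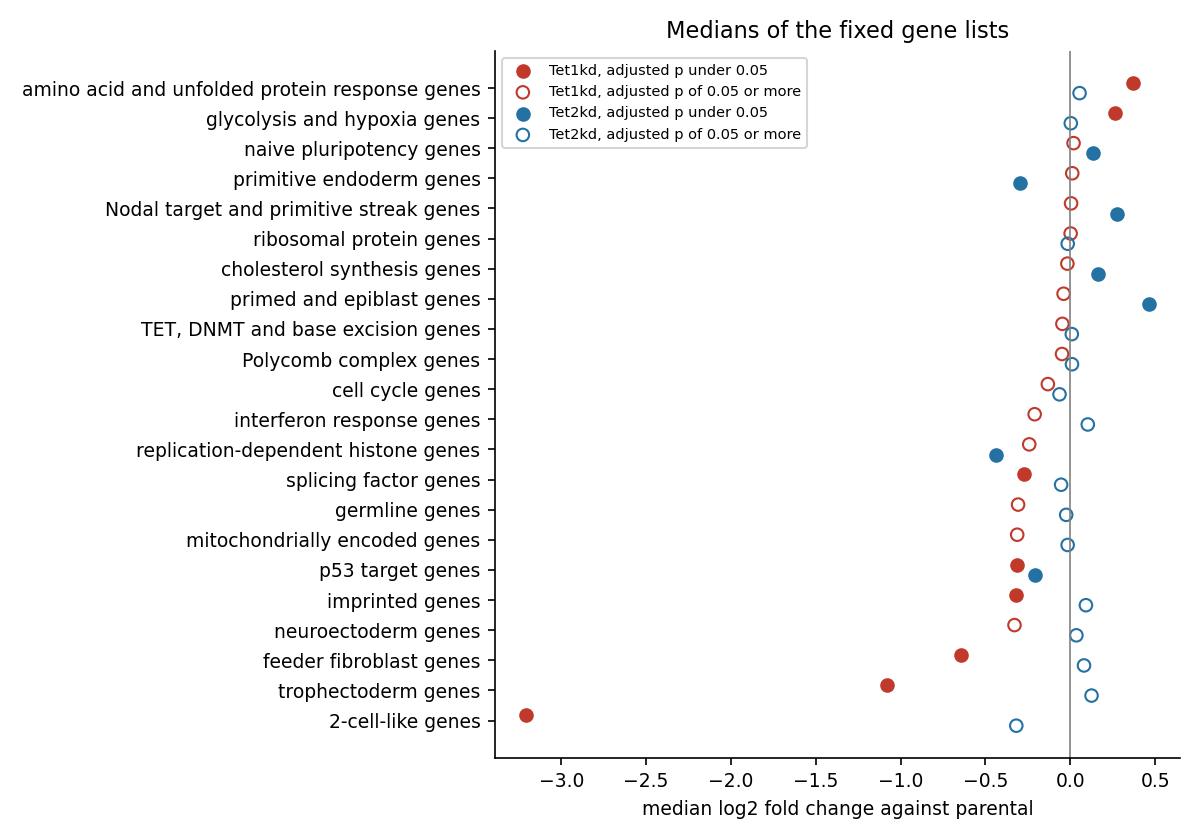
Median log2 fold change against parental of each fixed gene list in Tet1kd and Tet2kd cells, with the Y-linked list left out because its medians of -4.77 and -5.19 lie far outside the others. Filled points passed the test against random lists matched on mean expression, and p53 target genes lay below 0 in both knockdowns.

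Of the 72 genes named for this comparison and past the threshold, 67 had all single libraries recovered, and in these 67, chosen for passing the test, all 4 Tet2kd libraries lay on the side of the change. Calcoco2, Insig1 and Hist1h1c stayed past the threshold by limma in only 5, 4 and 4 of the 8 settings that leave out 1 library. The call of Calcoco2 ended without parental replicate d (adjusted p = 0.0516), Tet2kd replicate a (0.0562) and Tet2kd replicate c (0.0543). That of Insig1 ended without parental replicates c and d (both 0.0597) and Tet2kd replicates a (0.0687) and b (0.0519). That of Hist1h1c ended without parental replicates b (0.0509) and d (0.0725) and Tet2kd replicates a (0.0834) and d (0.069).

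The third comparison asked whether the knockdowns changed the same genes. Shared changes can also come from the vector, the selection and the picking of clones, which both knockdowns had in common. Of 22389 genes tested in both, 1065 were called in both, and 818 of these (76.8%) went the same way. There were 399 genes higher in both, where independent lists would share 138, and 419 lower in both, where they would share 119. Another 77 genes were higher in Tet1kd and lower in Tet2kd cells (118 for independent lists) and 170 were lower in Tet1kd and higher in Tet2kd cells (139). With limma over 10506 recovered genes 1387 were called in both with the same direction. With simulated unchanged groups against the same parental libraries a mean of 0.05 of these 10506 were. The simulated groups held no changed genes, so few calls in either comparison follow from the simulation itself. This value therefore does not tell how many shared calls noise of the parental libraries adds where genes do change.

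Genes that fell in both knockdowns included the Y-linked genes, Plac1 and the transporter genes Slc6a14 and Slc15a2. In the authors' deposited table the log2 fold changes in Tet1kd cells were -2.12 for Slc6a14, -1.94 for Slc15a2 and -2.02 for the predicted gene Gm22888. In all 4 Tet2kd libraries together Slc6a14 had 9 reads, Slc15a2 6 and Gm22888 1, so their log2 fold changes there are given as counting intervals of -4.16 to -1.98, -6.00 to -3.38 and -10.6 to -2.75. The purinergic receptor gene P2rx6 had no reads in any parental library and was at least 1.54-fold higher in Tet1kd and at least 1.42-fold higher in Tet2kd cells, from a floor of 3 reads per library. Genes that went opposite ways included Cubn, Pclo and the epiblast growth factor gene Fgf5. The log2 fold changes of Fgf5 were -1.98 in Tet1kd and 1.31 in Tet2kd cells in the authors' deposited table, and those of Pclo were -1.37 and 1.64. In the authors' deposited table those of Fbp2 were 1.78 and -2.23, of the opioid precursor gene Pdyn 1.90 and -1.73, of the cardiac actin gene Actc1 -2.53 and 1.40, of Catsperz 1.41 and -1.36 and of the mesenchymal factor gene Twist2 -2.49 and 1.31. Fbp2 had 10 reads in all 4 Tet2kd libraries together (counting interval -3.36 to -1.21) and Twist2 11 in all 4 Tet1kd libraries (-3.50 to -1.45).

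The difference between the knockdowns was also tested directly with limma, and 7148 of 14559 genes differed, with 3678 higher and 3470 lower in Tet1kd than in Tet2kd cells. T was lower in Tet1kd than in Tet2kd cells by a log2 difference of -4.48 (adjusted p = 1.63e-08), Zic2 by -2.34 (adjusted p = 2.16e-10) and Peg3 by -1.95 (adjusted p = 2.03e-10). Cubn was higher in Tet1kd cells, with a log2 difference of 3.60 (adjusted p = 4.44e-09), as were Fbp2 (4.65, adjusted p = 0.000575) and Pdyn (3.55, adjusted p = 2.23e-07). Fgf5 was lower in Tet1kd cells, with a log2 difference of -3.33 (adjusted p = 0.000148). For Otx2 the difference of 0.19 did not pass the test (adjusted p = 0.0508). Within the deeper and the shallower library batch the direct test called 6406 and 6049 genes.

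Across the 10700 genes with a mean of at least 100, which are not independent replicates, the log2 fold changes of the knockdowns had a Pearson correlation of 0.340, a Spearman correlation of 0.343 and a covariance of 0.0440. Over the recovered genes the correlation was 0.310 and the covariance 0.0439. With the parental libraries split, so that each knockdown was set against different ones, the correlation lay between 0.264 and 0.291. Unchanged groups simulated against the same parental libraries gave a correlation of 0.497 but a covariance of 0.0032, which left a difference in covariance of 0.0407.

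**Figure D3:**
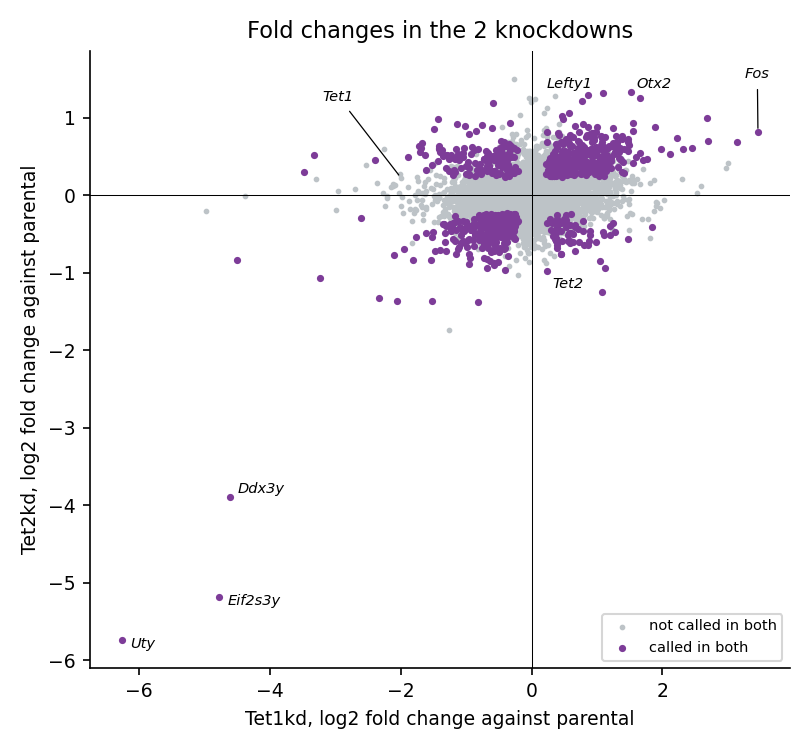
Log2 fold change against parental in Tet1kd cells (horizontal axis) and Tet2kd cells (vertical axis) of genes with a mean normalized count of at least 100 in both comparisons. Purple points were called in both knockdowns and grey points were not, and the Y-linked genes Uty, Eif2s3y and Ddx3y lie below -3 on both axes.

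The deposited tables also tested relative exon use, the share of a gene's reads that falls in each of its exon bins. In Tet1kd cells 5020 of 195843 bins in 2936 genes changed in the authors' deposited table, 2257 with a higher and 2763 with a lower share. In Tet2kd cells 4726 of 193091 bins in 2805 genes changed in the authors' deposited table, 2070 with a higher and 2656 with a lower share. Unlike the gene counts, the counts of bins were close to each other. Of the 2936 genes with a changed bin in Tet1kd cells 49.3% also changed at the gene level, against 45.6% of all genes tested for exon use, and in Tet2kd cells the shares were 12.4% and 10.8%. The ratios of bins are given as deposited, as knockdown over parental. The parental shares of bins from the 2 comparisons matched best when these ratios were multiplied by 2.

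The bins of Tet1 itself did not all fall alike in Tet1kd cells. Of its 27 bins, numbered along the genome, bins 2 (0.16) and 4 (0.15) had a higher share and bins 21 (-0.38), 22 (-0.50) and 25 (-0.13) a lower share of the reads of Tet1, as log2 ratios in the authors' deposited table. In Tet2kd cells Tet1 bins 2 (0.08) and 3 (0.18) had a higher and bins 8 (-0.51), 22 (-0.07) and 25 (-0.07) a lower share in the authors' deposited table. Of the 15 bins of Tet2, bin 1 (0.22) had a higher and bin 12 (-0.15) a lower share in Tet2kd cells in the authors' deposited table, and in Tet1kd cells bins 1 (0.06) and 6 (-0.28) changed. Both genes lie on the minus strand, so low bin numbers are at the 3' end. In both knockdowns the bins with a higher share thus lay nearer the 3' end than those with a lower share. This is the direction of the tilt in coverage described below, and whether that tilt accounts for these bins was not tested.

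In Tet1kd cells 77 bins were tied at a listed adjusted p of 0 in the authors' deposited table. The 10 genes named from these were taken by the size of their ratio. Of them the cytochrome b5 reductase gene Cyb5r1 had the largest log2 ratio (-2.14, bin 1 of 31). It was followed in the authors' deposited table by Tacc2 (-1.30), the autophagy gene Gabarap (-1.01), Luc7l2 (1.00), the joined genes Fbxo24 and Pcolce (-0.94), whose reads cannot be told apart, Tsc22d1 (0.84), Asxl2 (0.82), the helicase gene Ddx39 (-0.81), Zcchc7 (0.79) and Vps72 (-0.72). The bins of Luc7l2, Tsc22d1, Asxl2 and Zcchc7 were also called higher in Tet2kd cells. That of Tacc2, lower in Tet1kd cells, was called higher in Tet2kd cells. In Tet2kd cells 76 bins were tied at a listed adjusted p of 0 in the authors' deposited table. The 10 named by the same rule were led by the DNA polymerase subunit gene Pola2 (-1.18) and the ribosomal protein gene Rps21 (-0.91). Next came the glutamate receptor gene Grik3 (-0.91), Cabin1 (-0.80), the fatty acid synthase gene Fasn (-0.78) and the translation factor gene Eif4a2 (-0.76). Dnajc3 (-0.68), Vrk1 (-0.66), Fblim1 (-0.64) and Nol11 (-0.63) followed. Vrk1 also fell at the gene level, with a log2 fold change of -0.85 in the authors' deposited table. The bins of Pola2, Rps21, Grik3, Eif4a2 and Fblim1 were also called lower in Tet1kd cells. Those of the others named for Tet2kd cells were lower in Tet1kd cells too, without passing the threshold. The identifier of Eif4a2 joins overlapping genes whose reads cannot be told apart.

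The knockdowns shared many changed bins. Of 1064 bins called in both, 445 had a higher share in both, where independent lists would share 25.1, and 609 a lower share in both, where they would share 39.4, while 3 and 7 went opposite ways. The test of exon use shares the 4 parental libraries between the knockdowns, and the bins hold no reads per library from which this could be simulated. Last bins at the 3' end were called more often than inner bins, at 5.51% against 2.41% in Tet1kd and 5.62% against 2.30% in Tet2kd cells. These bins were not matched on read count, so the rates do not separate position from the number of reads. Of the last bins called, 452 of 577 in Tet1kd and 520 of 581 in Tet2kd cells had a higher share.

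Genes were also compared by chromosome, since the knockdown clones were picked singly. In Tet1kd cells the median log2 fold change differed from the other chromosomes on chromosomes 6 (-0.21), 8 (-0.09), X (-0.10), 2 (0.06), 15 (0.06) and 17 (0.06) by a permutation test with adjusted p from 0.000133 to 0.0357. In Tet2kd cells it differed on chromosomes 8 (-0.11), 14 (-0.05), 17 (0.04), 7 (0.03), 9 (-0.03), 10 (0.03) and X (0.03), with adjusted p from 0.000133 to 0.0386. With genes of a mean count of at least 1000 chromosomes 6 and 8 in Tet1kd cells and 7, 8 and X in Tet2kd cells remained past the threshold. Chromosome 8 was lower in both knockdowns, and 58.5% and 68.8% of its genes lay below 0.

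The shift of chromosome 6 came from a block of neighbouring genes, found after the data were examined. From Rbpj-ps3 to Suclg2, 179 of the 497 genes of the chromosome had a median log2 fold change of -0.89 in Tet1kd cells, 165 of them (92.2%) below 0. Of these genes 149 were lower and 3 higher in the authors' deposited table. The rest of the chromosome had a median of -0.00097 and the same genes a median of 0.03 in Tet2kd cells. From Mapk1ip1 to Ptdss2 on chromosome 7, 30 genes had a median of 0.60 in Tet1kd cells (0.10 in Tet2kd cells). From Thoc3 to Pcbd2 on chromosome 13, 29 genes had a median of 0.58 in Tet2kd cells (0.01 in Tet1kd cells) and 0 of them lay below 0. Each of these blocks had the smallest p that 1000 permutations of gene order can give (0.001). A block of 152 genes on chromosome 2 from Rbm18 to Madd had a weaker shift in Tet1kd cells (-0.14, permutation p = 0.023), and in simulated orders with no block 2 such blocks arose in 20 runs.

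**Figure D4:**
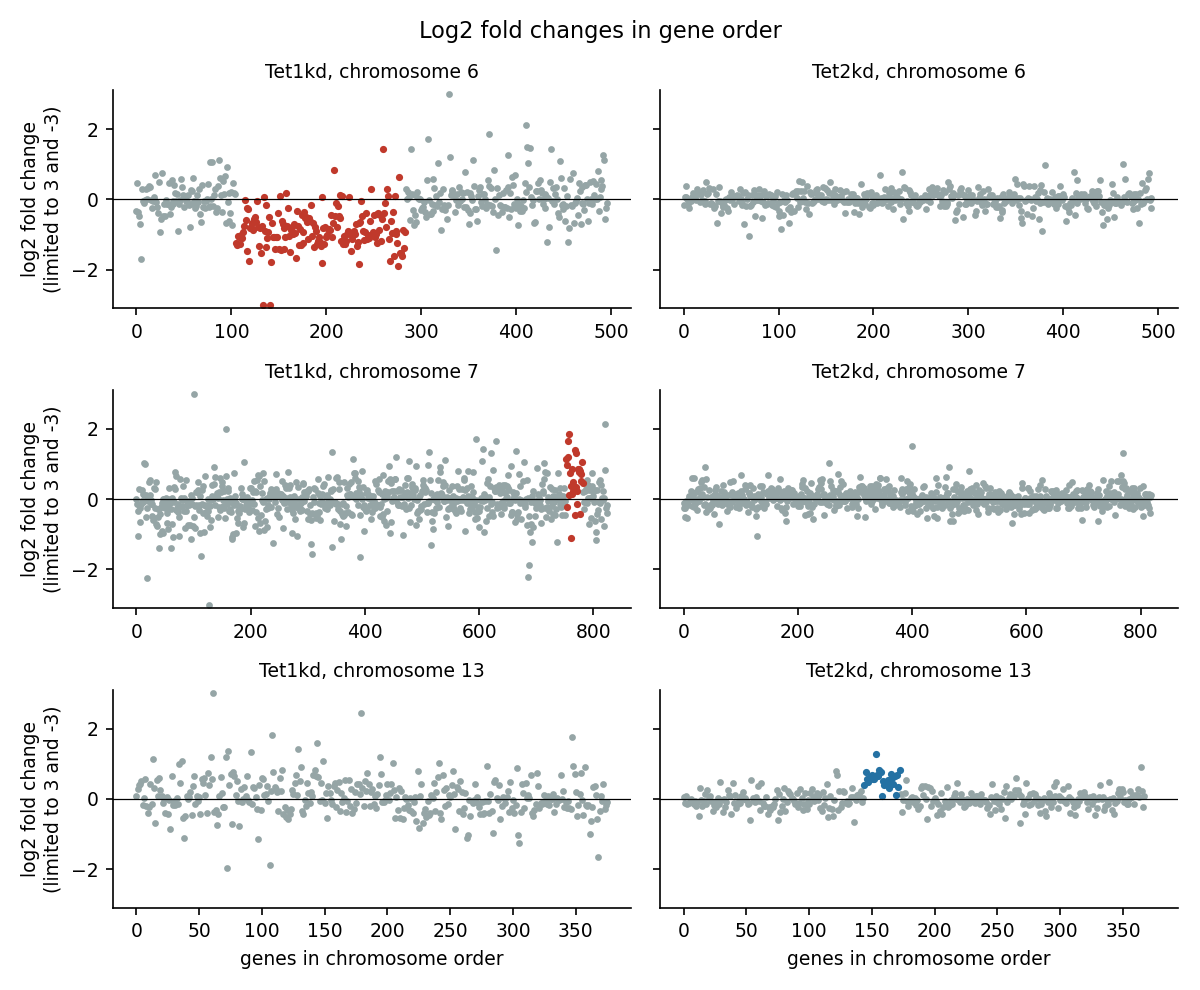
Log2 fold change against parental of genes with a mean normalized count of at least 100 in their order along chromosomes 6, 7 and 13 (from top to bottom) in Tet1kd cells (left) and Tet2kd cells (right), with values beyond 3 or -3 drawn at 3 or -3. Grey points are genes, and the coloured points are the genes of the blocks with medians of -0.89 and 0.60 in Tet1kd cells (red) and 0.58 in Tet2kd cells (blue).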

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

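The tests of Y-linked genes, of copy number, of expression classes within the blocks, of the lowest library, of the last 3' bins alone, of shared noise and of other splits of the libraries were chosen after the results were seen, while the ranges across libraries, the matched genes and the coverage of all shared bins were set down beforehand.

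The Y-linked genes Uty, Eif2s3y and Ddx3y kept 1.31% to 6.75% of their parental means in the knockdown cells. Feeder cell RNA in the parental libraries alone would have taken the feeder fibroblast list down with them. The median of that list in Tet2kd cells was 0.081 (quartiles -0.18 and 0.40), with the abundant Col1a1 at 0.49, which argues against it there. In Tet1kd cells, where 21 of 30 members fell, the median was -0.64 (quartiles -1.2 and -0.18). Dcn reached -4.98 and Mmp3 -3.41 there, with Col1a1 at -0.31. The members thus fell too unevenly for the median to settle whether feeder RNA was lost in Tet1kd cells. Reads moved to the X-linked copies would have raised Eif2s3x, whose higher log2 fold change was -0.10, and a line with 2 active X chromosomes would have raised X-linked genes, whose higher difference to the other chromosomes was 0.032. A loss of the Y chromosome in the cells that gave rise to the knockdown cells, or another line with 1 X and no Y chromosome, may account for it and was not tested. No biological explanation by Tet1 or Tet2 was tested, since the labels do not tell how many lines a knockdown has.

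The blocks of neighbouring genes on chromosomes 6 and 7 in Tet1kd cells and 13 in Tet2kd cells were weighed against technical sources, and genes matched on GC content, transcript length and mean count carried at most 5.12% of the shift. The medians of the 4 libraries ranged over up to 35.9% of the shift (chromosome 7), which lay between the limits set beforehand and decided nothing alone, but the library nearest to 0 still carried 72.8% or more of the shift, which argues against 1 library or library batch. A change in copy number may account for the block medians, since the folds were 0.539, 1.52 and 1.49 and the one furthest from 0.5 or 1.5 was 0.539, with limits chosen after these folds were seen, but alone it would give 1 fold at every expression level. From the lowest to the highest of 3 expression classes the medians were -0.72, -0.87 and -1.0 on chromosome 6 (Spearman correlation with mean count -0.206, p = 0.00578), 0.90, 0.78 and 0.37 on chromosome 7 (-0.230, p = 0.222) and 0.57, 0.64 and 0.57 on chromosome 13 (-0.212, p = 0.269). No DNA was measured, so copy number alone or with a further change, and an effect of the knockdown on neighbouring genes, stay open.

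Of the exon bins called in both knockdowns 99.1% went the same way. Noise of the shared parental libraries, a like response of both knockdowns, or the vector, selection and cloning they had in common would each give this. These cannot be told apart without reads per library for each bin and a group with a control hairpin. Of the bins called in the same direction 17.6% were first or last bins, below the limit set beforehand for coverage tilted towards the 3' end. Such a tilt would also move inner bins, whose position was not examined. This share therefore does not tell how much of the whole a tilt accounts for. For the last 3' bins called higher in both, such a tilt may be the source: among bins that were not called, last 3' bins lay above inner bins by 0.018 in Tet1kd and 0.027 in Tet2kd cells, and 63.9% and 71.9% of them lay above 0 against 49.5% and 49.7% of inner bins. No biological explanation was tested.

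Each limma comparison of 8 libraries was set beside all 35 splits into 4 and 4, of which 1, the real one, called as many genes. The other splits mix libraries of both groups, so any difference between the groups widens their spread and lowers their calls. The splits therefore show that libraries resembled others of their group. They do not separate an effect of the knockdown from a difference between lines. The real splits called 7921 genes (Tet1kd against parental), 2680 (Tet2kd against parental) and 7148 (Tet1kd against Tet2kd), and the highest other splits 134, 1419 and 108. In each comparison the highest other split followed the library batch, and within the deeper and the shallower batch the real contrasts called 7696 and 7112, 3090 and 2620, and 6406 and 6049 genes.

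Single libraries stood apart from the other 3 of their group in 7 of 254 groups of named genes, where chance gives about 1 in 20 groups (12.7), by the gap to the nearest library over the range. They were Zscan4d (0.901, parental d lowest), Hist2h4 (0.870, parental c highest), Rpl39l (0.849, Tet1kd b highest), Pclo (0.902, Tet2kd b highest), Trpm1 (0.832, parental b highest), Dnmt3l (0.905, Tet2kd d lowest) and Esrp2 (0.95, Tet2kd a lowest).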

How the results depend on the processing

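The tests with limma, the second deposited p-value, the library batch, camera, the genes of the blocks and of the Y chromosome, the rescaled exon ratio, the parental mean of list members and all alternatives to the bins called in both were chosen after the data were examined. Counts moved with the threshold by construction. At an adjusted p of 0.01 there were 975 genes in Tet2kd cells, 469 genes in both knockdowns, 2345 exon bins in Tet1kd cells, 2232 in Tet2kd cells and 461 in both, and at 0.1 there were 8058, 7631 and 1837 bins. With Bonferroni adjustment 2763 genes were called in Tet1kd and 364 in Tet2kd cells, and with a log2 fold change of at least 1 in size 1910 and 193. With a log2 ratio of at least 1 in size 620 and 462 bins were called, and 1455 and 1104 after multiplying by 2. Without bins of genes called at the gene level 2523 bins were called in Tet1kd cells and 462 in both. The second deposited test called 4171 genes in Tet2kd cells and 2244 in both, and limma called 2680 in Tet2kd cells, or 5313 with the library batch as a term; the cause was not tested. The correlation between the knockdowns was 0.312 for genes with a mean of at least 10, 0.305 without Y-linked genes and 0.360 without genes of the blocks. With an estimated correlation camera called 2 lists in each knockdown, against 9 and 8 with random lists, and with genes of a mean of at least 1000 there were 2 chromosomes in Tet1kd and 3 in Tet2kd cells; the cause was not tested. A mean of at least 100 over both groups is a limit that the change itself moves. Of the lists that passed with all members, it turned the direction of trophectoderm genes in Tet1kd cells (0.24, adjusted p = 0.396) and primitive endoderm genes in Tet2kd cells (0.031, adjusted p = 0.721). With a parental mean of at least 100 these were -0.52 (adjusted p = 0.0042) and -0.015 (adjusted p = 0.946), and 2-cell-like and histone lists had too few members. Lists that passed in neither setting also turned with a mean of at least 100 over both groups. Among them were primed and epiblast genes in Tet1kd cells (0.13) and trophectoderm genes in Tet2kd cells (-0.11). The direction of trophectoderm genes in Tet2kd cells turned by the mean (-0.21, adjusted p = 0.0419) and with a parental mean of at least 100 (-0.20, adjusted p = 0.0198), and the cause was not tested. Leaving out each library in turn, limma called 7291 to 7585 genes in Tet1kd cells, 1935 to 2371 in Tet2kd cells and 6496 to 6845 between the knockdowns. Among counts and values that answer a comparison, 21 planned and 56 added alternatives kept the main result within its limits. Another 16 planned and 13 added alternatives moved it beyond these limits. Among lists, chromosomes and named genes, 163 planned and 379 added alternatives kept the side of the threshold, 11 lost the threshold and 5 gained it. In a further 3 planned and 1 added alternatives the direction turned. Directions were compared only where either value passed the threshold. Some results that passed in neither setting turned, such as Nodal target genes in Tet1kd cells by the mean (-0.59, adjusted p = 0.0504 against random lists). No paired analysis was possible because the recovered libraries carry no replicate numbers, so the only blocked fit was the one with the library batch as a term. The tests with edgeR and DESeq2 on counts per sample were not run because the tables hold none. Depth limits the genes with few reads, and at these depths limma called 48, 44 and 42 of 100 genes with the smaller simulated change.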

Other observations

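The genes of the first paragraph, which were not tested as a set, and the X-linked copies were chosen after their values were seen, and the test of chromosome 8 was set down before the 4 parts of the chromosome were examined.

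Of the genes induced by growth signals that were looked up beside Fos, Fosb and Egr2, 7 rose in Tet1kd cells. Myc, Fosl1, Dusp5, Spry4 and Dusp6 fell. The log2 fold changes in the authors' deposited table were -2.61 for Myc, 2.70 for Egr1, 1.53 for Dusp1, 1.39 for Egr3, 1.16 for Junb, 1.06 for Jun, 1.05 for Zfp36 and 0.85 for Ier2. They were -2.99 for Fosl1, -1.12 for Dusp5, -1.07 for Spry4 and -0.96 for Dusp6 in the authors' deposited table. In Tet2kd cells the log2 fold changes in the authors' deposited table were 0.81 for Fos, 0.71 for Egr1 and 0.69 for Fosb, all past the threshold, and 0.42 for Egr2 (adjusted p = 0.0705) and 0.34 for Jun (adjusted p = 0.0639). Myc (-0.29), Spry4 (-0.52) and Dusp5 (-0.69) fell there and Dusp6 (0.28) and Zfp36 (0.26) rose in the authors' deposited table, while Egr3, Junb, Ier2, Dusp1 and Fosl1 were not past the threshold.

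The X-linked copies of the Y-linked genes had log2 fold changes in the authors' deposited table of -0.33 and -0.10 for Eif2s3x, -0.41 and -0.02 for Kdm6a and -0.39 and -0.08 for Ddx3x in Tet1kd and Tet2kd cells.

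Chromosome 8 was lower in both knockdowns, and a candidate explanation is that it was gained in part of the parental cells that both were compared with. A gain of the whole chromosome would lower each of 4 equal parts of its genes in both knockdowns, and the highest of the 8 medians was -0.063. The parts in gene order had medians of -0.06, -0.07, -0.08 and -0.10 in Tet1kd cells and of -0.08, -0.07, -0.12 and -0.15 in Tet2kd cells. Noise of the shared parental libraries that differs by chromosome stays open, and no DNA was measured.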
